A study of Olea europaea var. sylvestris with 6 samples.

How the data were processed

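RNA was sequenced from the stems of wild olive (Olea europaea var. sylvestris) plants of 2 genotypes, AC15 and AC18, with 3 biological replicates of each, giving 6 libraries. According to the labels' protocols the plants were untreated, grew on their own roots from rooted cuttings, were 6 to 10 months old and 40 to 52 cm tall, and spent 2 months in a greenhouse before the experiment. Poly(A) RNA was made into strand-specific libraries and read as 100-base pairs on an Illumina HiSeq instrument, per the labels' protocols. A poly(A) selection leaves out transcripts without a tail, so the values describe polyadenylated RNA.

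The deposited table gives estimated counts, 1 row per identifier and 1 column per library. The submitters' processing notes name FastQC, Trimmomatic and kallisto 0.46.1. kallisto assigns reads to transcripts without aligning them base by base and divides reads that match several transcripts among them, so its counts are estimates. The transcript reference, the genome build and any step that turned estimates into whole numbers are not given in the sources used here. The values deposited by the authors are whole numbers with a different total in each library, so they were used as deposited, without further rounding. The table holds 50668 rows, of which 16777 have no count in any library. No identifier before its suffix occurs on more than 1 row, so no rows were summed, and each row is called a gene below.

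The identifiers of the table could not be joined to gene names: 0 of the 50668 identifiers were found in the RefSeq table of 47911 wild olive genes. Names, functions and positions of genes are therefore not used here. A set of 29 gene lists (defence proteins, resistance genes, receptor kinases, lignin and other pathways, hormone signalling, markers of other stem tissues) had been fixed before the data were examined as patterns of product names, and 0 of them could be run. The rule for the genes named in the text was fixed at the same time. It takes, per direction, the 2 genes with the largest fitted fold change among those with an adjusted p under 0.05, a mean of at least 3 on the log2 CPM (counts scaled by the normalized total of their library) scale, and no overlap between the libraries of the genotypes. The rule had wider parts that needed product names, and these were not used.

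Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM normalization, genotype as the single factor, two-sided). Genes with low counts were first removed by edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 24018 genes that held 99.72% of all counts. P-values were adjusted by the Benjamini-Hochberg method, and a gene is called where the adjusted p was under 0.05. The test was against no difference. A call of at least 2-fold is a called gene whose fitted fold change reached that size, and no test against 2-fold or a larger limit was run. Fold changes are AC18 minus AC15 on the log2 scale. The standard error of a fold change was taken from the fitted coefficient and its F statistic, and 95% intervals from the same fit were used to count genes whose difference was bounded. A separate count without a test took genes with no count (under 0.5) in all libraries of one genotype and at least 10 counts in each library of the other. Where a genotype had no count for a gene, its level was bounded at 3 counts summed over its 3 libraries. Measures with a single value per library were compared by a two-sided exact permutation test, which cannot give a p below 0.1 with 3 libraries against 3. The interval for the count ratio of a single gene is an exact binomial (Clopper-Pearson) interval at 95%. It and the floor cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules. Intervals for numbers of genes with reads in one genotype come from 5000 resamples of blocks of 100 consecutive identifiers.

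The totals ran from 7468058 to 8589143 counts per library. The median standard error of a log2 fold change was 0.141. The fit was tested on simulated data made from the real means, library totals and spread of this comparison (24018 genes, 200 of them changed). Of 50 genes changed at each size, 30.0% were called at 1.25-fold, 58.0% at 1.5-fold, 78.0% at 2-fold and 100.0% at 4-fold, none in the wrong direction, with 9 calls among 23818 unchanged genes. With only 200 changed genes, the adjusted p asks for a smaller unadjusted p than in the real comparison, where 14302 genes were called. The shares therefore do not estimate how many real differences of each size were missed.

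Equal replicate numbers in the labels were not treated as pairs. Nothing in the labels ties them, and the deviations of same-numbered libraries from their genotype means correlated at -0.03, -0.01 and -0.04. The labels name no sequencing batch or date. No 2 libraries agreed within sampling noise, so none was counted as a duplicate. The alternatives tried were the size factors of DESeq2, library totals alone, no filter, a filter of at least 1 CPM in 3 libraries, the tests of DESeq2 1.42.0 and limma 3.58.1 (voom), a replicate block, leaving out each library in turn, leaving out genes with reads in one genotype, and other limits for the latter. Figures were drawn with matplotlib 3.10.9.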

Results

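Stem transcriptomes of 2 varieties of wild olive were compared in the absence of any infection. AC18 is described by the submitters as tolerant and AC15 as susceptible to Verticillium wilt, the vascular disease caused by the soil-borne fungus Verticillium dahliae, which colonizes the xylem. The comparison asks how stem gene expression differs between the varieties before they meet the pathogen. Each genotype had 3 biological replicates. Each tolerance class is represented by a single variety, so the p-values compare these varieties and not tolerant with susceptible plants in general.

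The AC15 libraries held 7468058, 8489459 and 7485093 counts for replicates 1, 2 and 3. The AC18 libraries held 7912720, 7892188 and 8589143. Mean depth was 7814203 ± 584851 counts in AC15 and 8131350 ± 396593 in AC18 (SD, n = 3 each), and the difference was smaller than the spread between replicates (two-sided exact permutation test, p = 0.5). At least 1 count was recorded for 33891 of the 50668 genes in the table.

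More genes were detected in AC18 stems. At least 10 counts were reached by 23732 ± 243 genes per AC18 library and by 23062 ± 279 genes per AC15 library (SD, n = 3 each). After every library had been thinned to the total of the smallest, the numbers were 23466 ± 111 genes in AC18 and 22928 ± 53.2 in AC15 (SD, n = 3 each). The 3 AC18 libraries lay above the 3 AC15 libraries in both counts, and the exact permutation test gave its smallest possible two-sided p, 0.1, for each. This thinning equalized the totals only. A few very abundant genes took more of the counts in AC15, as given below, which leaves fewer counts for its other genes. How much of the difference in detected genes this accounts for was not tested. Whether AC15 lies further in sequence from the transcript reference, which could also lower its number, is not known here.

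The AC15 stem transcriptome was more concentrated in a few very abundant genes. The 10 most abundant genes of each library took 7.59% ± 0.697 of its counts in AC15 and 4.98% ± 0.271 in AC18 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). The single most abundant gene of a library took 1.90% ± 0.0755 in AC15 and 1.14% ± 0.0306 in AC18. Of the 10 genes with the highest mean share over all 6 libraries, 8 were called higher in AC15 by edgeR's test with an adjusted p under 0.05, and the other two were not called.

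Genotype was the main axis of variation. The first principal component of the log2 CPM values separated AC15 from AC18 and carried 87.8% of the variance, against 4.4% for the second. Pearson's r across the tested genes was 0.862 to 0.870 for the 9 pairs of libraries from different genotypes. It was 0.982 to 0.988 for the 3 pairs within AC15 and 0.988 to 0.990 for the 3 pairs within AC18. The part of the transcript pool that differed between paired libraries (the Bray-Curtis dissimilarity of their CPM values) was 17.4% to 18.7% between genotypes, 3.75% to 6.15% within AC15 and 3.35% to 4.73% within AC18. Replicate 2 of AC15 stood somewhat apart from the other AC15 libraries. Its chi-square per gene was 4.83 against replicate 1 and 4.47 against replicate 3, where replicates 1 and 3 gave 1.79 and a value near 1 would mean sampling noise alone. Without this library 14332 of 24464 tested genes (58.6%) were called, against 14302 of 24018 (59.5%) with it. Of the calls made with all libraries, 92.5% recurred in the same direction without it.

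A large part of the expressed stem genes differed between the genotypes, about equally in both directions. Of 24018 genes tested, 14302 (59.5%) were called, 7086 higher in AC18 and 7216 higher in AC15 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The share was 48.8% at an adjusted p under 0.01, 46.9% of 33891 genes without the filter on low counts, and 41.8% of the 29948 genes that DESeq2 tested. Most of the differences were modest. The median absolute log2 fold change of called genes was 0.73, and for 9440 of them the fitted difference was less than 2-fold. The values of the 3 AC15 and the 3 AC18 libraries did not overlap for 15211 genes (63.3%), where chance alone gives 10%. They did not overlap for 13602 of the called genes (95.1%), which follows largely from the call, made on the same libraries.

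Genes with larger fitted differences were more often higher in AC18. The fitted difference was at least 2-fold for 4862 called genes (20.2% of those tested), 2702 higher in AC18 and 2160 higher in AC15. The limits here were set on fitted values, so the true difference of a gene near a limit may be smaller. At 4-fold or more the numbers were 1028 higher in AC18 and 613 higher in AC15. At 16-fold or more they were 345 and 155, respectively. A larger sequence distance of AC15 from the transcript reference could contribute to this excess and was not tested. The genes at least 2-fold higher in AC18 took 10.6% ± 0.094 of the counts in AC18 and 3.28% ± 0.038 in AC15 (SD, n = 3 each). The genes at least 2-fold higher in AC15 took 11% ± 0.52 in AC15 and 3.93% ± 0.16 in AC18. These shares describe genes selected for the difference and are not a further test of it.

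**Figure D1:**
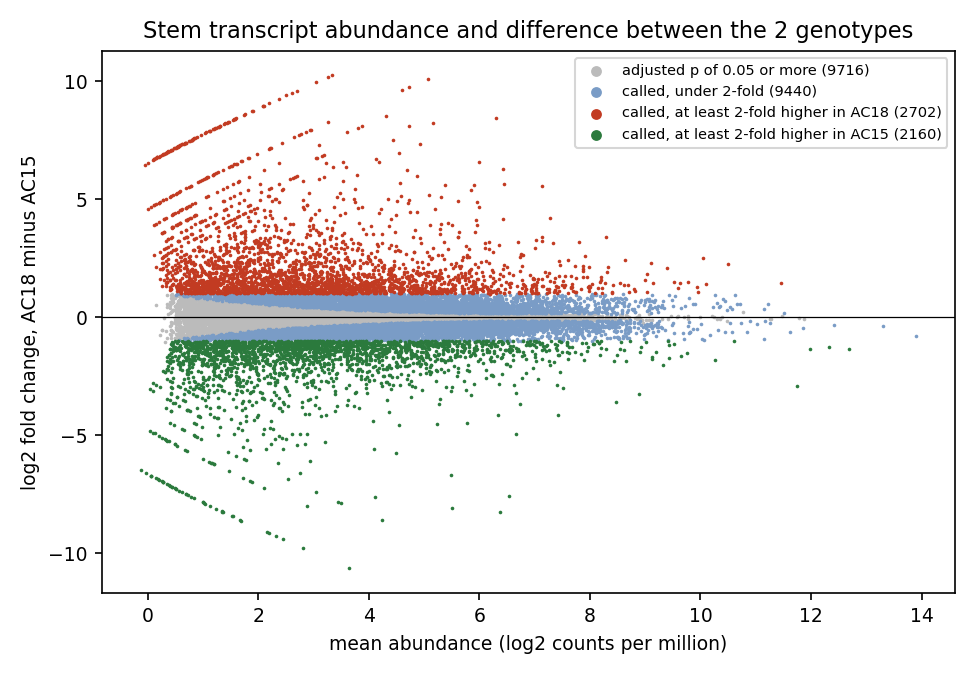
Each point is 1 of the 24018 tested genes, with mean abundance in log2 CPM on the horizontal axis and the fitted log2 fold change (AC18 minus AC15) on the vertical axis. Red points are the 2702 genes called at least 2-fold higher in AC18, green points the 2160 called at least 2-fold higher in AC15, blue points the 9440 called with a smaller difference and grey points the 9716 not called; the slanted lines of points at the left are genes with 0 or a few counts in one genotype.

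The difference between the genotypes could be bounded for a large part of the tested genes. The 95% interval of the fold change lay within 2-fold in either direction for 15479 genes (64.4%) and within 1.5-fold for 8613 (35.9%). Both sets include called genes, since a small difference can be called. The intervals were taken gene by gene, without adjustment for the number of genes, and rest on the TMM normalization. Of the 9716 genes not called, 6021 were bounded within 1.5-fold. For the remaining uncalled genes the interval was too wide for such a bound.

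The size of the fitted difference varied with abundance when the tested genes were split by mean abundance into 4 classes of equal size. In the least abundant class (0.922 to 5.45 CPM), 51.1% of genes were called and 36.4% were called with at least 2-fold. In the most abundant class (37.1 CPM and above), 69.3% were called but 11% reached 2-fold. The median standard error of the log2 fold change fell from 0.31 in the lowest class to 0.08 in the highest, so small differences could be called mainly among abundant genes. The larger error also widens the spread of fitted fold changes in the lowest class. A gene near the limit of the filter passed it if 1 genotype alone reached that limit. The 36.4% and 11% therefore do not estimate how true differences vary with abundance. In the lowest class 1709 genes were called higher in AC18 and 1360 higher in AC15. In the highest class 1897 were called higher in AC18 and 2262 higher in AC15, but this balance turned to 2115 and 2025 when libraries were scaled by their totals alone.

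**Figure D2:**
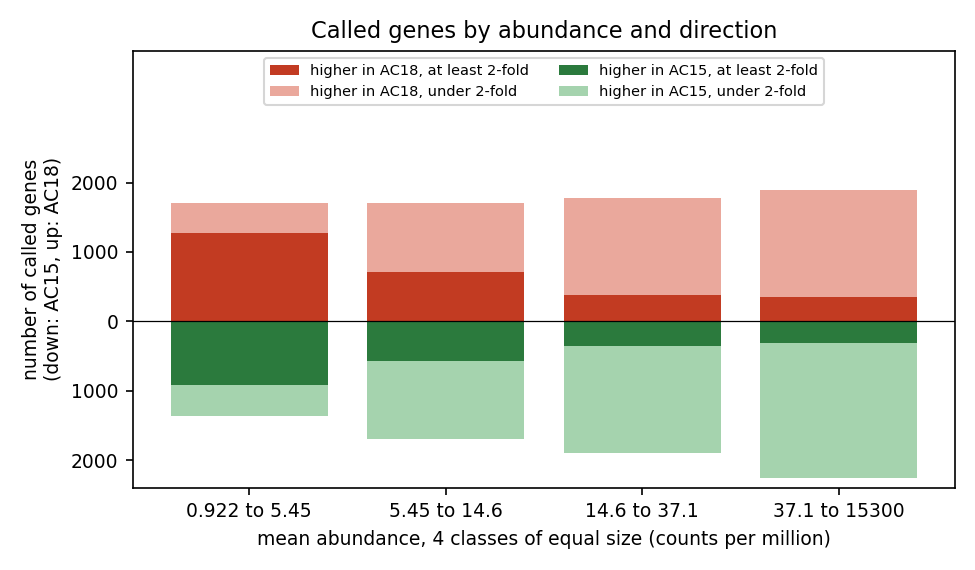
Bars give the number of called genes in each of 4 equal classes of the 24018 tested genes by mean abundance in CPM, upward for genes higher in AC18 and downward for genes higher in AC15, with dark parts for differences of at least 2-fold. The dark parts shrink from 1268 and 918 genes in the lowest class to 347 and 311 in the highest.

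Some genes gave reads in a single genotype. Under the limit of at least 10 counts in each library of one genotype and none in the other, 104 genes had reads in AC18 alone and 46 in AC15 alone. The total of 150 depended on the limits: it was 274 with at least 5 counts, 64 with at least 20 counts, and 388 when at most 2 counts were allowed in the other genotype. AC18 thus held 69.3% of the 150 such genes (95% interval 61.2% to 77.2%, from resampling blocks of 100 consecutive identifiers, since neighbouring genes are not independent). They were mostly of low abundance, with a median of 21.5 counts per library for the AC18 genes and 21.7 for the AC15 genes, and together they took 403 CPM in AC18 and 194 in AC15. Among the 104 genes, 96 passed the abundance filter and each of these was called, as were all 46 of the AC15 genes. The way these genes were selected made such calls all but certain, so the calls are no further evidence.

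The 4 named genes had no counts or almost none in one genotype. They were selected for a large difference between these same libraries, so their adjusted p-values are no further evidence. Oeu019835.1 had 150, 144 and 178 counts in the AC18 libraries and 0 in each AC15 library. Its level in AC18 was 19.0 ± 1.1 CPM (SD, n = 3), at least 146-fold higher than the 0.13 CPM that 3 counts over the AC15 libraries would give (edgeR adjusted p = 2.8e-17). Oeu043575.1 had 132, 137 and 179 counts in AC18 and 0 in each AC15 library, a level of 18 ± 1.9 CPM (SD, n = 3) that was at least 138-fold higher by the same floor (edgeR adjusted p = 7.8e-17). In the other direction, Oeu019520.1 had 205, 181 and 189 counts in AC15 and 0 in each AC18 library. Its 25.2 ± 3.4 CPM (SD, n = 3) in AC15 was at least 206-fold higher than the AC18 floor of 0.121 CPM (edgeR adjusted p = 4.1e-18). Oeu055163.2 had 275, 317 and 279 counts in AC15, or 37.9 ± 0.4 CPM (SD, n = 3), and 0, 0 and 2 counts in AC18. The AC15 to AC18 ratio was 468, with a 95% counting interval of 129 to 3872 (edgeR adjusted p = 4.8e-21). Both AC18 counts came from replicate 3. Without that library the AC15 level was at least 199-fold higher than 3 counts summed over the remaining AC18 libraries would give. The fitted log2 fold change then moved from -8.62 to -11.2. The files do not pair these identifiers with gene names, so what the genes encode and where they lie is not given here. Reads of near-identical copies may have been divided between identifiers by the counting, so a count of 0 shows that no reads were assigned to that identifier.

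**Figure D3:**
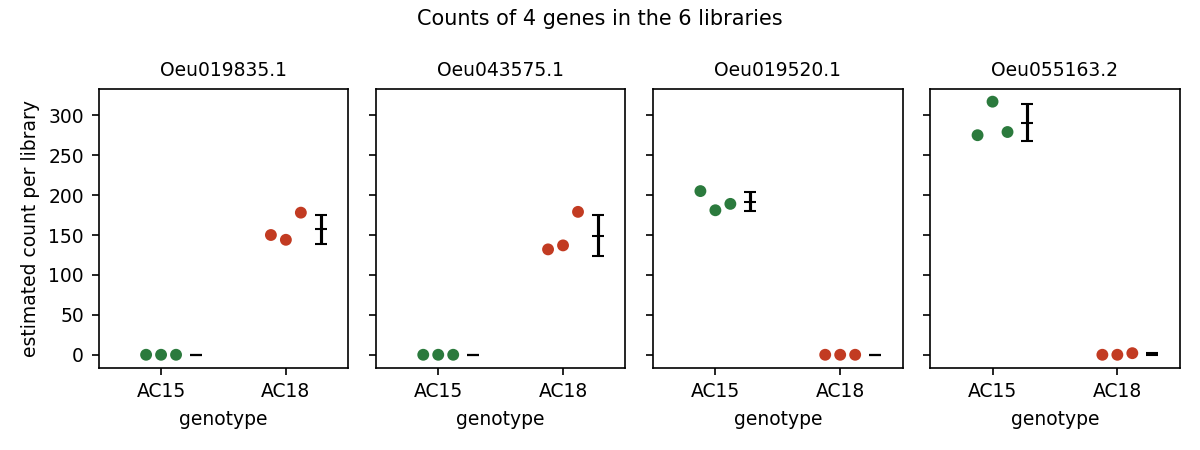
Estimated counts per library of 4 genes in the 3 AC15 libraries (green) and the 3 AC18 libraries (red), with the mean and SD of each genotype in black beside the points. Oeu019835.1 and Oeu043575.1 lie between 132 and 179 counts in AC18 and at 0 in AC15, while Oeu019520.1 and Oeu055163.2 lie between 181 and 317 counts in AC15 and at 0 to 2 in AC18.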

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

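The alternatives were chosen before the data were examined, except the thinning and the stricter adjusted p. The count of 14302 genes stayed within 1.5 times under each alternative run: 14278 with the size factors of DESeq2, 14163 with library totals alone, 15887 without a filter (46.9% of 33891 genes tested), 14615 with a filter of at least 1 CPM in 3 libraries, 12516 with DESeq2's own test (41.8% of 29948), 14215 with limma voom, 14153 without the genes that had reads in one genotype, and 11732 (48.8% of 24018) at an adjusted p under 0.01. The called share of tested genes was 52.6% to 59.5% in the other fits, so a majority of genes was not called under these 3 alternatives, 2 of which tested more genes. DESeq2 called 81.5% of the same genes in the same direction and the other settings just listed, apart from the stricter p, 95.1% or more. No gene called by both was called in opposite directions. The share of calls higher in AC18 was 49.5% and ranged from 49.4% to 54.0% over all settings, with 54.0% from library totals alone. Which genotype had more calls in total depended on the scaling, the filter, the test and the libraries kept. Among calls of at least 2-fold, AC18 held 54.7% to 59.0% in every setting. Leaving out each library in turn gave 12893 to 14332 calls, and 5056 to 5267 calls of at least 2-fold. A replicate block gave 14191 calls. Same-numbered libraries did not deviate together, 0 of the 6 libraries correlated best with the library of its own number, and the labels do not tie the numbers. The count of genes with reads in one genotype depended on its limits, by their construction. It was 274 (185 in AC18, 89 in AC15) with at least 5 counts, 64 (42 and 22) with at least 20 counts, and 388 (271 and 117) when at most 2 counts were allowed in the other genotype. Leaving out a library gave 166 to 192. AC18 held more of these genes than AC15 under each of these limits. For the 4 named genes, all 53 values under alternatives kept the direction with an adjusted p of at most 2.6e-13. These genes were selected for a large difference between the same libraries, which made this all but certain, so it is no further evidence. The size of the fitted difference did vary. By limma voom the log2 fold changes were smaller for the 3 genes with no count in one genotype. They were 8.19 for Oeu019835.1, 8.11 for Oeu043575.1 and -8.68 for Oeu019520.1, against 10.25, 10.17 and -10.64. The log2 fold change of Oeu055163.2 ranged from -11.2 to -8.12 when single libraries were left out. Camera tests of the gene lists were not run, since no product names could be joined, and a comparison of transcript with gene level was not run because each identifier has a single row.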

Other observations

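Apart from the count over other splits of the libraries, the tests here were chosen after the pattern they concern had been seen. Gene names were not available, so these observations rest on counts alone.

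More genes had reads in AC18 alone (104) than in AC15 alone (46), a ratio of 2.26 (1.58 to 3.38, 95% interval over resampled blocks of 100 consecutive identifiers). Fewer counts left for most genes in the AC15 libraries, which are more concentrated in a few genes, were tested by thinning every library to 6874718 counts after removal of the 10 most abundant genes. The numbers were then 90 and 46, a ratio of 1.96 (1.35 to 2.95), which argues against depth as the whole cause. Reads assigned instead to a copy with a neighbouring identifier would raise such neighbours in AC15, but the 216 tested genes within 3 identifiers had a median log2 fold change of 0.07 (bootstrap 95% interval -0.05 to 0.20), which leaves this open, since few of these neighbours need be copies and copies can lie elsewhere. A difference between the varieties in the presence or the activity of these genes, and a larger sequence distance of AC15 from the transcript reference, may each account for the pattern and could not be separated without sequence.

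The number of called genes, 14302, was set against the other splits of the 6 libraries. Of the 10 splits into 3 and 3, 1 (the real one) called as many genes, and the highest of the others was 0 by edgeR's adjusted p and also 0 by limma voom, with 39 to 194 genes at an unadjusted p under 0.05 by edgeR. Each of the other splits mixes the genotypes, so the difference between genotypes enters the spread within their groups. Few or no calls there were fixed in advance, and no conclusion is drawn from them. These splits are also too few for a share under 0.05. An error of scaling between genotypes as the whole cause is argued against by calls in both directions, 7086 higher in AC18 and 7216 higher in AC15. The lowest count under any common shift of the log2 fold changes from -1 to 1 was 14235. It follows from that balance and is not a separate test. Separate handling of the genotypes cannot be told apart from genotype: the component that carries 87.8% of the variance separates exactly the labelled genotypes, and no batch is named. The calls range from 9440 differences under 2-fold to 345 and 155 genes at least 16-fold higher in AC18 and AC15, and whether handling could produce differences as large as the latter was not tested.

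Genes with consecutive identifiers tended to differ in the same direction. Over 11285 pairs of tested genes with consecutive numbers, Spearman's rho of the log2 fold changes was 0.063 across genes, which are not independent replicates, against an upper limit of 0.018 for the central 95% of 1000 shufflings (permutation p = 0.001, the smallest they can give). Both members were called at least 4-fold in 93 pairs, where shufflings gave 53 on average and 67 at the upper limit of their central 95%, and 70 of the 93 (75.3%) went in the same direction against 53.2% when directions were shuffled (one-sided permutation p = 1e-04, the smallest possible). Unevenness between single libraries, unrelated to genotype, should also appear within a genotype, where the largest rho of the 6 pairs of libraries was 0.02, slightly above the limit of the shufflings. Log ratios of 2 single libraries carry more counting noise than fold changes fitted over all 6, which pulls their rho toward 0. This comparison therefore cannot exclude such unevenness. Unevenness that coincides with genotype, through separate handling, stays open as well. Reads shared between near-identical copies were tested through the levels of pair members, and the explanation was narrowed to an equal split only after the result had been seen: the 70 same-direction pairs differed by a median of 1.53 on the log2 CPM scale (bootstrap 95% interval 1.08 to 1.95), against 1.09 to 1.99 for random pairs of such genes. The lower end reaches the limit set for an equal split, so shared reads stay open. If the identifiers follow the genome, which the sources used here do not state, a candidate explanation is that neighbouring genes share differences between the varieties, such as a segment present or active in one of them.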
